A study of Mus musculus with 6 samples.

How the data were processed

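Ribosome-bound RNA was obtained by immunoprecipitation of tagged Rpl22 from frontal cortex, and libraries were made with a stranded total RNA kit (SMARTer, Takara), per the labels' protocols. Reads were aligned with STAR to mm10, per the submitters' processing notes. The version of STAR, the counting tool, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may have been shared or dropped. The authors deposited raw counts per gene symbol, whole numbers with no normalization, for 23306 rows. Of these, 27 carried symbols that a spreadsheet had turned into dates, which were kept under those names, and 4 shared a repeated symbol and were kept apart. Genes encoded by the mitochondrial genome were not tested.

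Genotypes were taken from the labels, and replicate numbers were given in accession order and pair no samples. A column of the table was used where its name matched the title of a single sample. This held for 4 columns; 2 columns were not used, because both carry the title of wild type replicate 1 and no name tells which, if either, belongs to knockout replicate 2. The design had foreseen 3 libraries against 3, and the comparison is therefore 2 against 2. No pair of the 4 libraries agreed within sampling noise: the chi-square statistic per degree of freedom ranged from 3.15 to 6.73. Correlations of log2 CPM lay between 0.9907 and 0.9925 for pairs of different genotype, a range that held both pairs of the same genotype (0.9916 and 0.9912).

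The counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, genes kept by filterByExpr (12449), robust quasi-likelihood fits of knockout against wild type, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values use TMM-scaled library sizes unless they describe marker levels, which use library totals. The libraries held between 9696126 and 10301280 counts, and the median standard error of a log2 fold change was 0.13. Gene lists, 35 in all, and the rule for naming genes were fixed before the data were examined. The rule named Fxr1, Fxr2, Fmr1, Cacna1h, Pvalb and Rpl22. It also took up to 12 genes per direction past the threshold, with at least 10 CPM and groups that did not overlap, filled to 5 per direction by the smallest unadjusted p. Of each list described it took the 2 to 4 members with the smallest p, but for some lists fewer or none are named below. Cacna1g and Cacna1i are named as the other T-type channel genes, not by their p. Other genes named, such as cell type markers, serve as background levels or were chosen after their values were seen. Lists with at least 4 measured members (32) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), beside camera with an estimated correlation and fry. Coordinates are from the GENCODE M21 annotation of mm10 by gene symbol, which placed 11684 of the tested genes.

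The edgeR test was tested on simulated data drawn from the means and sizes of these 4 libraries, with 12322 genes tested. It recovered 86.6% of 67 genes changed 1.5-fold, all at 10 CPM or more, and all of those changed 2-fold or 4-fold. There were 4 false calls among 195. The simulated counts were independent between genes, varied by the overall dispersion trend alone and held no structure between libraries other than genotype. These figures may therefore not hold for the real counts. Alternatives tried were DESeq2 size factors, library totals, the Wald test of DESeq2 1.42.0 and limma voom. Filters tried were none on low counts and at least 5 CPM in 3 libraries. Also tried were non-robust fits, a test against a fold of 1.2, a threshold of 0.1 and other windows around Fxr1. Each library was left out in turn. Another alternative left out ribosomal RNA and small-RNA genes but kept ribosomal protein genes. A model with an added term for a split of the libraries was tried after seeing the data.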

Results

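RNA bound to tagged ribosomes was sequenced from parvalbumin neurons, the fast-spiking inhibitory interneurons of the cortex, in the frontal cortex of male C57BL6 mice. The mice carried either a conditional knockout of Fxr1, a gene for an RNA-binding protein of the fragile X family, or wild type Fxr1. In RiboTag mice, Cre recombinase driven by the Pvalb promoter switches on a haemagglutinin-tagged copy of the ribosomal protein Rpl22, so that an antibody pulls down ribosomes with their transcripts mainly from Cre-expressing cells. The series holds 6 libraries, 3 per genotype, of which 4 were analysed: wild type replicates 2 and 3 and knockout replicates 1 and 3. Their total counts ranged from 9696126 to 10301280. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

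Transcripts of parvalbumin neurons stood high in all 4 libraries. Gad1, which encodes a GABA-synthesising enzyme, averaged 4235 ± 133 CPM (counts scaled to a common library total; SD, n = 4), the potassium channel gene Kcnc1 1714 ± 100.3, and Pvalb itself 254 ± 10.9. Markers of other interneurons were low, with Sst at 9.73 ± 0.751 CPM and Vip at 1.12 ± 0.354 CPM. Transcripts of excitatory neurons and glia were also present: Camk2a averaged 698 ± 28.3 CPM, the excitatory vesicular transporter gene Slc17a7 79.2 ± 8.33 CPM and the astrocyte transporter gene Slc1a2 472 ± 35.2 CPM. Camk2a and Slc1a2 thus stood above Pvalb, and the nuclear noncoding RNA Malat1, at 7643 ± 481 CPM, above Gad1. No input fraction was analysed here, so enrichment by the pull-down was not measured. Knockout replicate 1 stood apart in the ribosomal RNA precursor Rn45s, which took 0.711% of its counts, against 0.283% to 0.315% in the other 3 libraries.

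The first comparison asked whether the Fxr1 transcript was reduced in the libraries labelled knockout. Fxr1 (mm10 chromosome 3, 34019943 to 34070322) fell from 99.6 ± 2.41 CPM in wild type to 18.3 ± 0.381 CPM in knockout (SD, n = 2 each), which is 18.3% of the wild type level. The libraries held 954 and 1036 Fxr1 counts in wild type and 181 and 192 in knockout. The log2 fold change was −2.45 with a standard error of 0.10, at an adjusted p of 1.77e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333, which Fxr1 reached. The paralogs of Fxr1 did not pass the test: Fxr2 had a log2 fold change of 0.16 (SE 0.08) and Fmr1 of 0.02 (SE 0.08), the latter turning to −0.03 without knockout replicate 3. Of the 10 measured genes of the Fragile X family and its partners, Fxr1 alone passed, both over all genes and adjusted over the list alone.

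**Figure D1:**
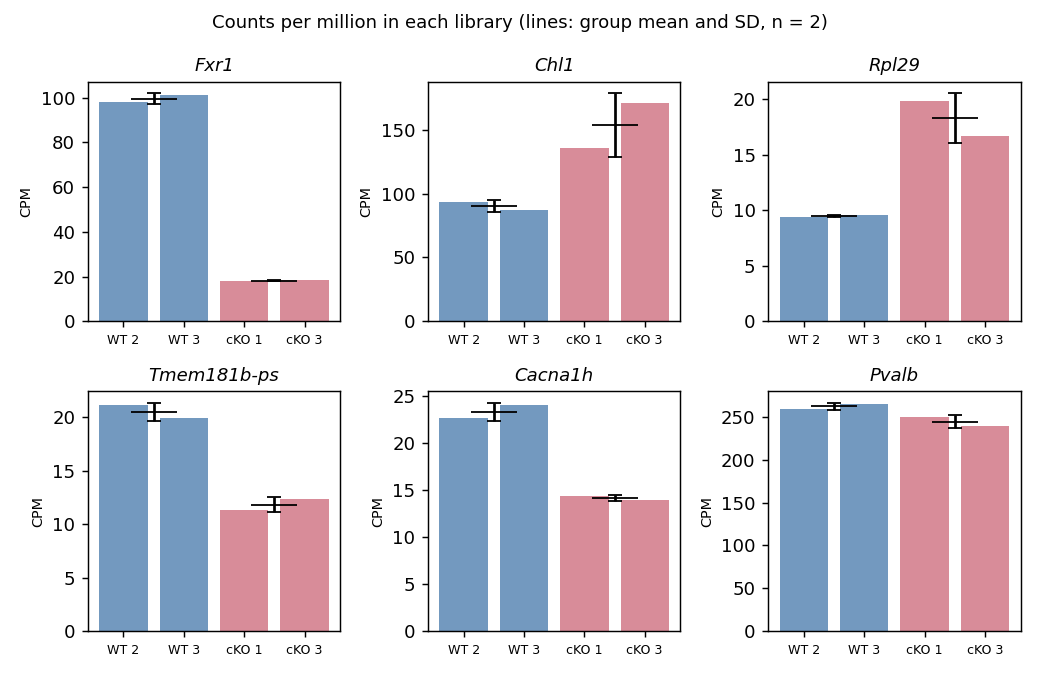
CPM (vertical axes, from 0) of 6 genes in each of the 4 libraries, wild type in blue and knockout in red, with horizontal marks and bars for the group mean and SD (n = 2 each). Fxr1 averages 99.6 CPM in wild type and 18.3 CPM in knockout, while Pvalb differs by a log2 fold change of −0.10 that did not pass the test.

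The second comparison asked which other ribosome-bound transcripts differed between the genotypes. Chl1, which encodes a neural cell adhesion molecule of the L1 family, rose from 90.2 ± 4.56 to 154 ± 24.9 CPM (log2 fold change 0.77, SE 0.10; adjusted p = 0.00134 by edgeR). Rpl29, a ribosomal protein gene, rose from 9.51 ± 0.101 to 18.3 ± 2.25 CPM (log2 fold change 0.94, SE 0.16; adjusted p = 0.0151 by edgeR). The transcribed pseudogene Tmem181b-ps fell from 20.5 ± 0.842 to 11.8 ± 0.722 CPM (log2 fold change −0.79, SE 0.15; adjusted p = 0.0399 by edgeR). Each value is a mean ± SD over 2 libraries, and both knockout libraries lay on the same side of both wild type libraries for each gene. With Fxr1, these made 4 of 12449 tested genes, 2 higher and 2 lower in knockout.

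Chl1 lies on chromosome 6 at 103510586 to 103750211, Rpl29 on chromosome 9 at 106429454 to 106431568 and Tmem181b-ps on chromosome 17 at 6438524 to 6467022. Ribosomal protein genes have many processed pseudogenes, and Tmem181b-ps belongs to a family of similar copies, so the counts of both may share reads with other loci. An unadjusted p under 0.05 was reached by 402 genes, fewer than the 622 that chance alone would give. The groups did not overlap for 30.1% of tested genes, against 33.3% by chance. Setting wild type replicate 2 and knockout replicate 1 against the other libraries gave 1492 genes with such a p. That difference counts as spread within both genotypes here, so these p-values may be too large. A count below chance therefore does not show that few transcripts differed. Genes that came next in either direction, named by the same rule, did not pass: Cntn6 (log2 fold change 0.47), Fat4 (0.52) and Lrsam1 (0.37) were higher in knockout, and Pla2g7 (−0.44) and Aff2 (−0.42) lower. Without single libraries the number of genes past the threshold was 9 (without wild type replicate 2), 25 (without wild type replicate 3), 29 (without knockout replicate 1) and 48 (without knockout replicate 3). It was 1 with library totals in place of TMM, 2 by DESeq2 and 13 with no filter on low counts. Tmem181b-ps lost its call without wild type replicate 2 (adjusted p = 0.157) and, among other settings, by DESeq2 and limma voom, and Rpl29 lost its call by DESeq2 (adjusted p = 0.457).

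The third comparison concerned Cacna1h, the gene of a T-type calcium channel, chosen because the published study of this mouse line singled it out. Cacna1h (chromosome 17, 25374285 to 25433783) measured 23.4 ± 0.974 CPM in wild type and 14.2 ± 0.296 CPM in knockout (SD, n = 2 each), with 221 and 246 counts against 145 and 145. Its log2 fold change was −0.72 (SE 0.14). The adjusted p over all genes was 0.052 by edgeR, which misses the threshold, and 0.000438 when adjusted over the list alone; since the study chose this gene, the latter is not independent evidence. Of the 21 voltage-gated calcium channel genes, 0 passed over all genes and 1, Cacna1h, adjusted over the list alone. The other T-type channel genes did not pass either, with log2 fold changes of −0.13 (SE 0.19) for Cacna1g and −0.12 (SE 0.08) for Cacna1i. As a group these genes did not pass, with 8 higher and 13 lower in knockout (adjusted p = 0.364 by camera). The adjusted p of Cacna1h by edgeR was 0.00231 with no filter on low counts, but 0.126 with library totals and 0.107 with non-robust fits. It was 0.99997 by DESeq2. The log2 fold change was −0.76 and −0.67 without wild type replicates 2 and 3, and −0.74 and −0.70 without knockout replicates 1 and 3. Each of these fits leaves a genotype with a lone library, so effect sizes alone are given for them.

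**Figure D2:**
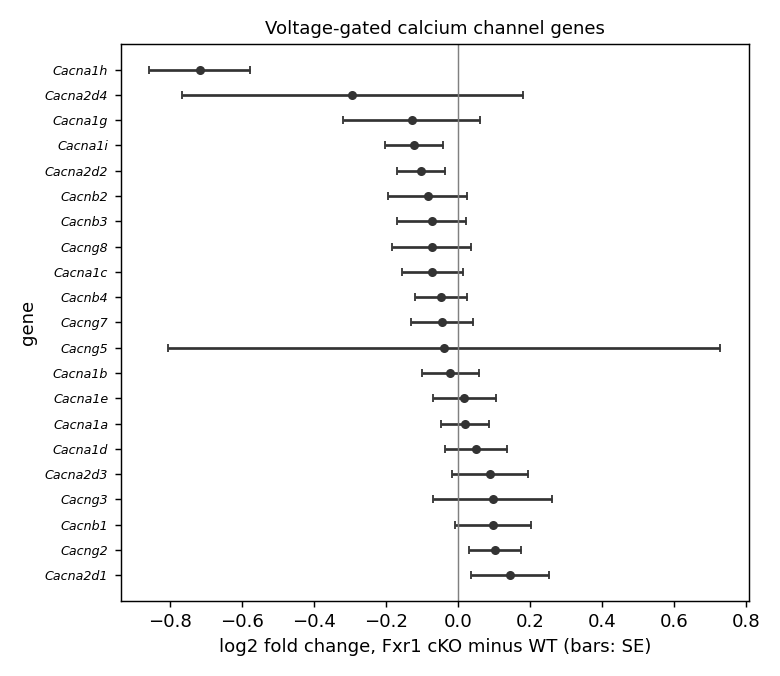
Log2 fold change of knockout over wild type (horizontal axis) for the 21 voltage-gated calcium channel genes (vertical axis), with standard errors as bars, from 2 libraries per genotype. Cacna1h, drawn at the top, has the most negative value, −0.72 with a standard error of 0.14.

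The fourth comparison asked whether groups of genes moved together. Cytosolic ribosomal protein genes were lower in knockout as a group, with 55 of 75 measured members below and 20 above wild type. The median log2 fold change was −0.07 (adjusted p = 0.00181 by camera with a preset correlation and 0.774 with an estimated correlation). It was −0.12 without wild type replicate 2 and −0.04 without wild type replicate 3. Relative to the wild type mean, this list averaged −0.039 and 0.039 (log2) in wild type replicates 2 and 3 and −0.066 and −0.050 in knockout replicates 1 and 3. Rpl29, which passed over all genes and adjusted over the list alone, went the other way, while Rpl17 (−0.32), Rps21 (−0.31) and Rpl10 (−0.33) did not pass. Synaptic adhesion genes were lower as a group, in 21 of 26 members, with an adjusted p of 0.0231 (adjusted p = 0.774 with an estimated correlation). The genotypes overlapped in this list, which averaged −0.03 and 0.03 (log2, relative to the wild type mean) in wild type replicates 2 and 3 and −0.07 and −0.02 in knockout replicates 1 and 3. Cntnap3 had a log2 fold change of −0.27 and Cdh13 of −0.16, while Elfn1, with the second smallest p of the list, went the other way at 0.52 (SE 0.19), and 0 members passed over all genes or adjusted over the list alone. Without wild type replicate 3 neither list passed (adjusted p = 0.392 for ribosomal proteins and 0.44 for synaptic adhesion), and synaptic adhesion did not pass without knockout replicate 1 either (adjusted p = 0.282).

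Lists with higher values in knockout included heat shock response genes, 12 of 13 members. The chaperone gene Hsph1 led them at a log2 fold change of 0.21. Relative to the wild type mean, this list averaged −0.035 and 0.035 (log2) in wild type replicates 2 and 3. It averaged 0.131 and 0.123 in knockout replicates 1 and 3. The adjusted p of the list was 0.0231 by camera and 0.774 with an estimated correlation. The call was lost without wild type replicate 2 (adjusted p = 0.449) and without knockout replicate 3 (adjusted p = 0.13). Genes of the integrated stress and unfolded protein response were higher in 10 of 17 members (adjusted p = 0.0358 by camera; adjusted p = 0.774 with an estimated correlation). Of these, 0 passed over all genes and 3 adjusted over the list alone: Calr (0.25, SE 0.07), Pdia4 (0.28, SE 0.08) and Hspa5 (0.21, SE 0.07), which encode chaperones and a disulfide isomerase of the endoplasmic reticulum. The genotypes overlapped in this list, whose mean log2 CPM was 5.53 and 5.86 in wild type replicates 2 and 3 and 5.62 and 5.87 in knockout replicates 1 and 3. The direction of the camera test turned to lower without wild type replicate 2 (adjusted p = 0.0222), where the median log2 fold change stayed above 0 at 0.0344, and without knockout replicate 3 (adjusted p = 0.393), where the median was −0.0081.

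Lists of other cell types and of RNA quality were tested alike. Oligodendrocyte and precursor markers were higher in 13 of 16 members (adjusted p = 0.0101 by camera; adjusted p = 0.774 with an estimated correlation), with Mal at a log2 fold change of 0.35 and Mobp at 0.24. The libraries of the genotypes overlapped: relative to the wild type mean, the list averaged 0.03 and −0.03 (log2) in wild type, −0.07 in knockout replicate 1 and 0.44 in knockout replicate 3. Without knockout replicate 3 the direction turned, at an adjusted p of 0.612, and without wild type replicate 3 the adjusted p was 0.0633. Striatal neuron markers were higher in 8 of 11 members, such as Ppp1r1b at a log2 fold change of 0.38 and Penk at 0.38. Relative to the wild type mean, this list averaged −0.014 and 0.014 (log2) in wild type replicates 2 and 3. It averaged 0.190 and 0.277 in knockout replicates 1 and 3. The adjusted p of the list was 0.0344 by camera and 0.774 with an estimated correlation. This call was lost whichever library was left out, at adjusted p values of 0.298 and 0.0633 without wild type replicates 2 and 3 and of 0.0516 and 0.458 without knockout replicates 1 and 3. The 4 measured ribosomal RNA and small-RNA remnants were higher as a group (adjusted p = 0.0344 by camera; adjusted p = 0.774 with an estimated correlation), with averages of 0.04 and −0.04 in wild type, 0.76 in knockout replicate 1 and −0.03 in knockout replicate 3; the direction turned without knockout replicate 1 (adjusted p = 0.264). No member of these 3 lists passed over all genes or adjusted over the list alone.

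In all, 7 of 32 tested lists passed by camera with the preset correlation, 0 with an estimated correlation and 0 by fry, whose lowest adjusted p was 0.556. By fry's test for change in either direction 3 lists passed: Fragile X family and partners, excitatory neuron markers and striatal neuron markers. The first of these holds Fxr1, the deleted gene, and no other member of it passed adjusted over the list alone. Its result therefore does not show a response of the rest of the family. The 25 measured parvalbumin neuron markers had a median log2 fold change of −0.02 and did not pass (adjusted p = 0.335 by camera). GABA synthesis, loading and uptake genes did not pass either (adjusted p = 0.536 by camera), nor did synaptic FMRP target transcripts (adjusted p = 0.866 by camera).

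The last comparison asked whether genes near Fxr1 differed more often. Of 60 tested genes within 10 Mb of Fxr1, 0 passed the edgeR test and 2 had an unadjusted p under 0.05. These were Fat4, 4.82 Mb from Fxr1 (log2 fold change 0.52, SE 0.11; adjusted p = 0.143 by edgeR), and Sec62, 3.20 Mb from it (0.22, SE 0.07; adjusted p = 0.998 by edgeR). Fat4 passed with no filter on low counts, without wild type replicate 2 and without knockout replicate 1. With 0 genes past the threshold near Fxr1 and 3 elsewhere, a one-sided Fisher's exact p is fixed at 1 and does not answer the question.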

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

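The model with a term for the library split was chosen after seeing the data; the other alternatives were fixed before the data were examined. The fall of Fxr1 passed under all 13 alternatives run for single genes, with log2 fold changes from −2.47 to −2.42. Chl1 passed in 12 of 13 and missed with library totals alone (adjusted p = 0.0563), Rpl29 in 10 and Tmem181b-ps in 7. The count of 4 changed genes (2 higher, 2 lower) became 1 (0 higher, 1 lower) with library totals, 2 (1 and 1) by DESeq2's Wald test, 13 (6 and 7) with no filter on low counts and 2 against a fold of 1.2. Under limma voom, at least 5 CPM in 3 libraries or non-robust fits, the number lower was 1. Leaving out each library gave 9 to 48 genes, 4 to 21 higher and 5 to 37 lower; a library left alone in its genotype is then assumed to vary like the other genotype. Cacna1h passed with no filter (log2 fold change −0.72, adjusted p = 0.00231 by edgeR). Its log2 fold change ranged from −0.76 to −0.67 over the libraries left out. Its adjusted p ranged from 0.000195 to 0.99997 over all alternatives. The added split term gave 39 genes, 20 higher and 19 lower, and Cacna1h at −0.72 with an adjusted p of 0.000195; this term was taken from the counts it was then fitted to, leaves 1 residual degree of freedom, and is no labelled batch, so these p-values are too small. The 7 gene lists became 4 with no filter, 3 with at least 5 CPM, and 0 with an estimated correlation or by fry. The direction of the value or of the camera test turned for Fmr1 (−0.0304 without knockout replicate 3, 0.0661 without knockout replicate 1), for the stress and unfolded protein list (adjusted p = 0.0222 without wild type replicate 2, with a median log2 fold change still above 0 at 0.0344, 0.393 without knockout replicate 3, against 4.17e-09 in the original direction without wild type replicate 3), for RNA remnants (0.264 without knockout replicate 1, against 3.08e-52 without knockout replicate 3) and for oligodendrocyte markers (0.612 without knockout replicate 3, against 3.74e-10 without knockout replicate 1). The cause of these changes was not tested. No paired analysis was possible because the replicate numbers come from accession order. Alternatives planned for normalized values were not run, since the values are counts. At these totals, of 9696126 to 10301280 counts, genes of a few CPM have large errors. Changes of 1.5-fold were partly missed in the simulated data. With 2 libraries per genotype, larger changes in the real counts missed the threshold too. Cntn4, with a log2 fold change of 1.22, had an adjusted p of 0.998 by edgeR, and Cacna1h, at −0.72, one of 0.052.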

Other observations

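Further genes of neuronal excitability did not pass as groups, as the calcium channel genes had not: of 33 voltage-gated potassium channel genes 14 were higher and 19 lower in knockout (adjusted p = 0.335 by camera), and of 16 sodium and HCN channel genes 7 were higher and 9 lower (adjusted p = 0.875 by camera). GABA receptor genes were lower in 13 of 15 members, with a median log2 fold change of −0.06 and an adjusted p of 0.101 by camera. Nos1, the neuronal nitric oxide synthase gene, measured 22.1 and 20.8 CPM in wild type and 15.8 and 15.5 CPM in knockout; it was the member of the somatostatin neuron list that passed when adjusted over the list alone (adjusted p = 0.0313 by edgeR) and did not pass over all genes (adjusted p = 0.998).

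In the tests that follow, the segment, engineered locus and depth tests were set before their results were seen; the pair, run, family, single-library and length tests were chosen after. Chl1, Cntn6 and Cntn3, all adhesion genes, lie in a row among tested genes on chromosome 6 and were higher in knockout, with log2 fold changes of 0.77, 0.47 and 0.46, of which Chl1 passed the test. Against a response of the whole gene family, 6 relatives on other chromosomes had a median of −0.0102 ± 0.0404 (log2), within a range from −0.178 to 0.0584. In this paragraph ± is a standard error of the median, from the median absolute deviation, and not an SD. Against a single library, both knockout libraries lay above both wild type libraries for each of the 3 genes. The median of the 3 genes stayed at 0.40 or more with any library left out, though they were chosen for their difference in these same libraries. The other 8 tested genes of the segment from Rybp (start 100228565) to Lrrn1 (end 107570214) had a median of 0.13 ± 0.05, below the bound of 0.2 set for an effect shared by all genes of the segment, but all 8 were above 0, and Cntn4, the contactin gene next to Cntn6, had the largest value of the segment, 1.22 (SE 0.39; 63.6 and 52.1 CPM in wild type, 100.3 and 169 CPM in knockout; adjusted p = 0.998), and passed with non-robust fits and without wild type replicate 3, knockout replicate 1 or knockout replicate 3, so an effect on this contactin stretch alone stays open. Whether the neighbourhood is chance stays open. Among 83 placed genes with p under 0.01, 13 pairs lay within 2 Mb, and 0.190 of random draws gave as many. That count covers the whole genome, and random draws mostly gave 4 to 18 pairs, so it cannot decide about a single group of 3 genes. A run as long as 3 came up in 0.00090 of shuffles. The run test was devised after the pair test had come out that way and the run had been noticed. It may overstate the case and alone decides nothing.

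Differences linked to the engineered alleles were looked for within 10 Mb of Fxr1, Rpl22 and Pvalb. An unadjusted p under 0.05 was found for 3.13% of 351 genes there and 3.26% of genes elsewhere (one-sided Fisher's exact p = 0.594; odds ratio 0.961, with a 95% interval from 0.471 to 1.76). For these 351 genes as a set, this argues against many linked differences. Tagged ribosomes were pulled down in both genotypes, so the Rpl22 and Pvalb alleles may not differ between them. Near Fxr1 itself lie 60 genes, of which 2 had an unadjusted p under 0.05. The pooled test therefore cannot decide about linked differences at Fxr1 alone, and single ones such as Fat4 stay open.

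Of the 3 ways to split the 4 libraries into pairs, too few for a test of chance, the one by genotype gave 4 genes, while setting wild type replicate 2 and knockout replicate 1 against the other two gave 239 and the third split 0, which points to a structure of the libraries other than genotype. Atf4, a transcription factor of the amino acid response chosen after its values were seen, measured 115 and 221 CPM in wild type replicates 2 and 3 and 117 and 207 CPM in knockout replicates 1 and 3, and Asns measured 104, 201, 112 and 179 CPM in that order. Depth is argued against as the cause, since the library totals differed little, from 9696126 to 10301280 counts. Thinning all libraries to the lowest total left 263 genes, but it removed at most 5.87% of counts and so could hardly have changed the number. Trends with transcript length or GC content are argued against as the whole cause, since their removal left 273 genes against 237 among genes with a length. The labels give no batch, animal or day, so a technical and a biological source may both apply. List tests and a cell type comparison across this split were run while exploring. They were left out because the split was picked by its outcome, and no biological explanation is drawn.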
